A study of Nicotiana benthamiana with 9 samples.

How the data were processed

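Small RNA was measured in 9 libraries of Nicotiana benthamiana line 16C leaves, 3 for each of the applied 22-nt siRNAs siR164, siR386 and siR739. Per the labels' protocols, RNA was extracted with a mirVana kit, small RNA was enriched, and libraries were made with the TrueQuant SmallRNA kit by a service provider. Bowtie2 is named in the submitters' processing notes. Its version and settings, the trimming of reads and the reference sequence are not given in the sources used here. The deposited values for each library are read coverage, as whole numbers per interval of a GFP contig of 792 nt, per the file headers. The name of each file says that all read lengths were used. The intervals count from 0 and are written here from position 1. Strands are together, reads of different lengths cannot be separated, and coverage was not divided by library size. Library totals were not analysed here, so a difference in raw coverage between libraries can come from the depth of sequencing as well as from the amount of transgene small RNA.

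The authors also deposited a table of normalized signal for the sum of 21-, 22- and 24-nt reads, with 1 column per siRNA and 772 positions. It pools the libraries of a group, so it has no replicate error. How it was scaled is not given in the sources used here. From its values, each entry appears to be a mean over 10 consecutive positions: undoing such a mean gave 0 values below 0 in each column, while undoing a mean over 6 to 9 or 11 to 14 positions gave 247 to 341. It was used for column sums, segment shares and the position of the maximum only, beside the values from the libraries, and to list single-position values for 1 further test. No other column of values was used.

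The sites were taken as 22 positions starting at the number in each name, 164 to 185, 386 to 407 and 739 to 760. Coverage was 0 there in the files, up to positions 188, 409 and 762 in at least 3 libraries, with the exceptions described among the closing observations. The segments were positions 1 to 163, 186 to 385, 408 to 738 and 761 to 792, and segment shares were taken of the coverage outside the sites.

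Groups and replicate numbers came from the sample titles. The design, the tests and most alternatives were fixed before the data were examined. The planned level was the authors' normalized value, but because that table is pooled, the main level was mean raw coverage per library. Levels were compared on log2(coverage + 1), so folds of low values are understated, with the F statistic over all 280 partitions of 9 libraries into 3 groups of 3, and pairs of groups with all 20 assignments of 6 libraries. Both are exact permutation tests and two-sided. The smallest p they can give is 0.00357 for 3 groups and 0.1 for a pair. Segment shares used the same test over 3 groups, with Benjamini-Hochberg adjustment over the 4 segments. Profile similarity was the mean Pearson correlation of log2(percent share + 0.1) over 32 windows of 25 nt, within groups minus between groups, with an exact one-sided permutation test over the same 280 partitions. The pseudocount of 0.1 was set after the files were seen and before any test.

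Windows were tested with limma (version 3.58.1, R 4.3.3; empirical Bayes with a trend, all 9 libraries in the fit) on log2(percent share + 0.1) for the profile and on log2(coverage + 1) for raw coverage. Windows with a mean coverage of at least 1 were tested, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The 6 windows that hold part of a site were tested with the others and counted apart, which left 26 windows. In raw coverage limma pooled the spread over all windows (192 degrees of freedom in total, against 12.6 in shares and 6 for a single window), although the windows of a library move together with its level. The calls in raw coverage are therefore stronger than 9 libraries support, and the exact tests of the level between libraries stand beside them. Coverage is not a count of reads, so no count model was used. The windows named are the 5 with the highest mean share in each group and, for each pair, up to 5 called windows outside the sites with the largest absolute log2 difference, with the most covered position of each group, the 3 sites and the 4 segments. Windows 576–600 and 676–725 in the pairwise comparisons, window 301–325 in shares and the windows with part of a site called in shares were named in addition, after their values were seen.

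The planned measure of the applied siRNA, 22-nt reads at its site, could not be taken because the sites are zeroed. It was replaced, after the data were seen, by the log2 ratio of coverage + 1 at the last position before the site to that 10 positions further 5', tested with an exact two-sided permutation of 3 against 6 libraries (84 assignments, smallest p 0.0119), adjusted over 3 sites. Shares 3' of the own site are means without a test.

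Replicates were compared with chi-square tests over the 26 windows, on coverage divided by 22 and rounded. The same test was run on the summed libraries of each siRNA, also without each library in turn, and on each replicate against the sum of the other 2 of its group; it replaced a rule on the lowest single library pair that had been tried before it. The window test was tried on simulated libraries (20 simulations per comparison, 6 changed windows, all 32 windows, negative binomial with a dispersion of 0.01, a floor set beforehand rather than an estimate). Of windows changed 2-fold it recovered 80% for siR386 against siR164, 86.7% for siR739 against siR164 and 76.7% for siR739 against siR386, and 100% of those changed 4-fold. The changed windows were drawn from those outside the sites above a minimum mean share. Windows of positions 1 to 150, 201 to 225, 251 to 275 and 776 to 792 lay below it, so these recovery rates do not cover them. Of unchanged windows in these simulations 1.5%, 5.75% and 5.75% were called, which includes the shift in shares that the changed windows bring, and 0%, 0.577% and 0.192% when nothing was changed.

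Alternatives were other pseudocounts, windows of 50 nt and of single positions, no filter, limma without the trend, quantile normalization, fits with the compared groups alone, sites left out, rank correlation, linear shares, distinct positions, and leaving out each library in turn. Masking the zeroed stretches alike in all libraries, subtracting the mean coverage of positions 1 to 100 (with values below 0 set to 0, and for the segments also kept), the 3' edges, and limma without moderation of the spread across windows were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.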

Results

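Small RNAs were sequenced from leaves of the Nicotiana benthamiana line 16C, which carries a green fluorescent protein (GFP) transgene, after synthetic 22-nt siRNAs against GFP had been applied by high-pressure spraying. Transitive silencing is the production of secondary small RNAs from parts of the transcript outside the siRNA's own site, through a plant RNA-dependent RNA polymerase and Dicer-like enzymes. The 3 siRNAs were siR164, siR386 and siR739, and each was represented by 3 libraries, numbered 1 to 3, 4 to 6 and 7 to 9. Each library came from 3 leaves with silenced areas, collected 6 days after spraying of 140 ng/µl small RNA. The numbers in the siRNA names matched the first positions of 22-nt sites on the 792-nt GFP contig of the files, to which all coordinates below refer. Where the transgene lies in the plant genome was not analysed here, nor were leaves without an siRNA. The values were read coverage per position, of all read lengths and both strands, not divided by library size. Summed over the contig, coverage was 124846, 37219 and 53991 in siR164 replicates 1 to 3, 22812, 40515 and 20325 in siR386 replicates 4 to 6, and 13059, 6536 and 8554 in siR739 replicates 7 to 9. At 22 nt per read these sums correspond to between 297 and 5675 reads per library, so profiles were least precise after siR739. Nothing in the labels said that libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical. Over the 26 windows outside the sites, no difference in relative profile was detected between replicate pairs (chi-square per degree of freedom from 0.458 to 1.19 over 9 pairs). Reads that span neighbouring windows are split in this test, which can lower the statistic, so spread beyond sampling noise is not excluded. Coverage sums of replicates differed, and all libraries were kept as separate samples.

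Coverage at each siRNA's own site was examined first, as a check of the labels. The sheets of the 3 siR386 libraries carry the name siR364, and the sample titles, which say siR386, were followed. The 22 positions of the sites held coverage of 0 in the files, with exceptions in 2 libraries at the siR164 site, so the applied siRNA itself could not be measured there and the steps in coverage at the site edges were used. At the 5' edge of the siR164 site, the log2 ratio of coverage at the last position before the site to coverage 10 positions further 5' was 2.15 ± 1.22 (SD, n = 3) in siR164 libraries and 0.017 ± 0.53 (SD, n = 6) in the others. At the siR739 site the same ratio was 1.23 ± 0.091 (SD, n = 3) in siR739 libraries and −0.024 ± 0.096 (SD, n = 6) in the others. At both sites the 3 libraries of the matching siRNA lay above the 6 others (adjusted exact permutation p = 0.0179, two-sided, adjusted over 3 sites). At the 5' edge of the siR386 site the difference was 0.34 and did not pass the test (adjusted exact p = 0.0952). It passed without siR386 replicate 5 (0.46, adjusted exact p = 0.0357) or without siR739 replicate 8 (0.41, adjusted exact p = 0.0357). At its 3' edge siR386 libraries were higher by 1.69 (adjusted exact p = 0.0357). The 3' edges of the siR164 and siR739 sites gave differences of 1.54 and 0.23 that did not pass (adjusted exact p = 0.179 and 0.560). The 5' edge measure was chosen after the data were seen, and so was the 3' edge. Without a library of siR164, or without siR739 replicate 7 or 9, the steps at the siR164 and siR739 5' edges had an adjusted exact p of 0.0536.

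The first comparison asked whether the applied siRNA changed the efficiency of transitive silencing, measured as the amount of transgene small RNA. Coverage was highest after siR164, at a mean of 90.9 ± 58.7 reads per position (SD, n = 3). After siR386 it was 35.2 ± 13.9 (SD, n = 3) and after siR739 it was 11.8 ± 4.22 (SD, n = 3). The 3 siR739 libraries, from 8.25 to 16.5, lay below the lowest siR386 library at 25.7 and the lowest siR164 library at 47.0, whereas siR164 and siR386 libraries overlapped. The 3 groups differed by more than the spread between replicates (F = 13.0 on log2(coverage + 1), exact permutation p = 0.00714, two-sided). On that scale siR386 minus siR164 was −1.22 (SE 0.59, exact p = 0.2), siR739 minus siR164 was −2.70 (SE 0.58, exact p = 0.1) and siR739 minus siR386 was −1.48 (SE 0.40, exact p = 0.1), where 0.1 is the smallest p that 3 against 3 libraries can give. Without siR164 replicate 1 the difference from siR164 was −0.74 for siR386 and −2.22 for siR739. In the authors' deposited table, which was normalized and pools the libraries of each siRNA, column sums over the 21-, 22- and 24-nt reads were 77880 for siR164, 35407 for siR386 and 10706 for siR739. The siR164 sum was thus 2.20 times that of siR386 and 7.27 times that of siR739 in the authors' deposited table, against 2.58 and 7.68 times for mean raw coverage. The raw folds lean on siR164 replicate 1, at 158 reads per position against 47.0 and 68.2 in siR164 replicates 2 and 3.

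**Figure D1:**
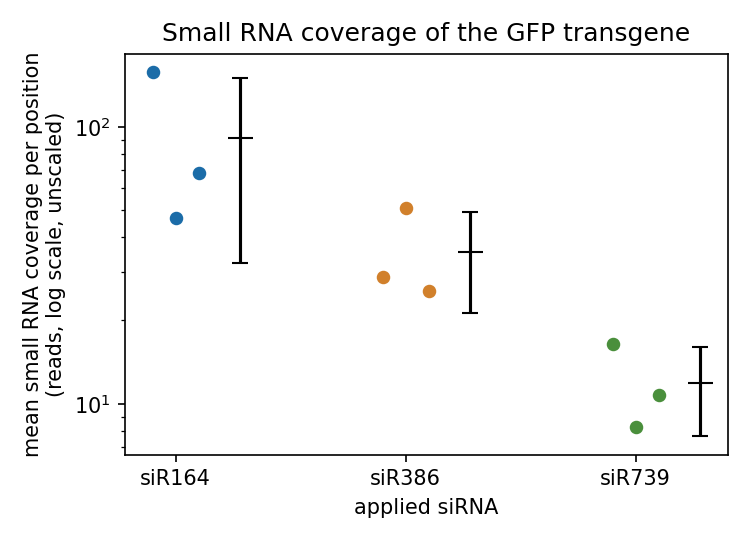
Mean small RNA coverage of the GFP contig (reads per position, log axis, not scaled for library size) for each library, by applied siRNA. Coloured points are libraries and black marks are the mean ± SD of 3 libraries, 90.9 for siR164, 35.2 for siR386 and 11.8 for siR739.

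The second comparison asked whether the profile of small RNAs along the transgene depended on the siRNA. Coverage was divided into 32 windows of 25 nt, each expressed as a percentage of the library's total. All 3 siRNAs gave their highest shares in the neighbouring windows 551–575 and 576–600. These windows held 10.8% ± 0.73 and 10.7% ± 0.58 after siR164, 12.5% ± 0.70 and 12.2% ± 0.49 after siR386, and 11.4% ± 1.34 and 9.72% ± 0.76 after siR739 (SD, n = 3 each). Window 501–525 was also among the 5 highest in each group, at 8.34% ± 0.57, 7.32% ± 0.47 and 6.65% ± 0.61. Windows 326–350 (6.96% ± 0.50) and 426–450 (5.95% ± 0.63) completed the 5 highest after siR164, windows 676–700 (6.78% ± 0.59) and 651–675 (5.84% ± 0.53) after siR386, and windows 676–700 (7.72% ± 0.34) and 701–725 (5.56% ± 0.98) after siR739. By the mean over libraries, the most covered position was 576 after siR164 (450 ± 253 reads) and siR386 (206 ± 70.4 reads). After siR739 it was position 763, the first past the zeroed siR739 site (59.3 ± 20.3 reads).

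On average, libraries of the same siRNA had more similar profiles than libraries of different siRNAs. The mean Pearson correlation of log2 shares across windows was 0.932 within groups and 0.881 between groups, a difference of 0.051 (exact one-sided permutation p = 0.00357, the smallest that the partitions of 9 libraries can give). Windows along a transgene are not independent replicates, and the test permuted libraries, not windows. Within groups it was 0.985 for siR164, 0.918 for siR386 and 0.893 for siR739. Between siRNAs, the mean correlation was 0.938 for siR386 and siR164, 0.868 for siR739 and siR386, and 0.837 for siR739 and siR164. The lower mean within siR386 came from replicate 6, which correlated at 0.898 and 0.884 with replicates 4 and 5, while these correlated at 0.973. The shares of replicate 6 include coverage at the siR164 site, which is 0 in most other libraries. Within siR739, replicate 8, the library with the fewest reads, correlated at 0.880 and 0.845 with replicates 7 and 9, while these correlated at 0.953. Replicate 8 also had the lowest correlation of its group with each library of the other siRNAs, and without it the means were 0.952 within and 0.912 between groups (exact p = 0.0107). Without siR164 replicate 1 or siR164 replicate 3, the differences within minus between were 0.038 and 0.036 and the exact p was 0.0571.

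**Figure D2:**
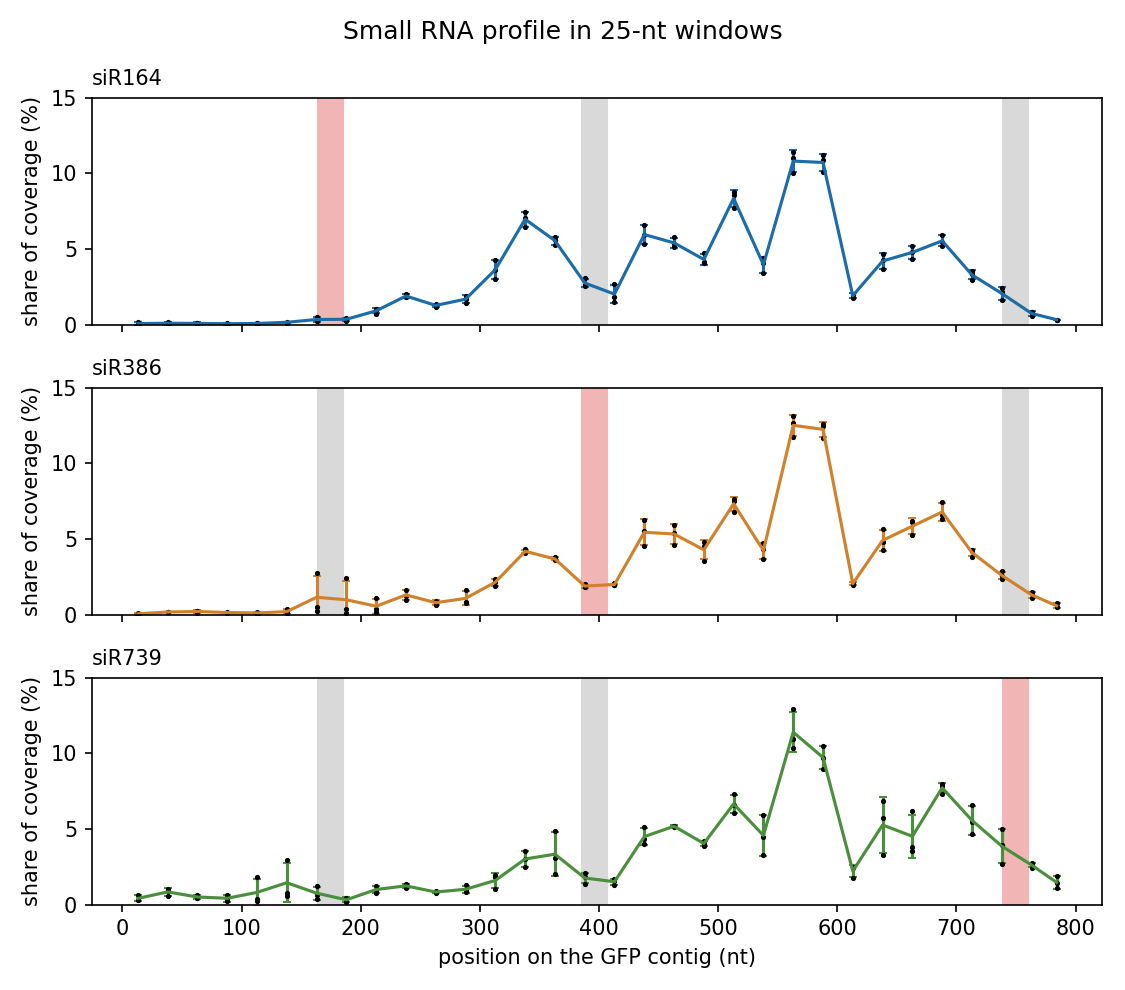
Share of small RNA coverage (%) in 25-nt windows along the GFP contig (position in nt), with 1 panel per applied siRNA. Lines and bars are the mean ± SD of 3 libraries, black points are libraries, the red band is the site of the applied siRNA and grey bands are the sites of the others. The highest shares lay in windows 551–575 and 576–600 in all 3 panels, and the share of window 326–350 was 6.96% after siR164, 4.18% after siR386 and 3.01% after siR739.

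The 3 sites divide the contig into 4 segments, fixed before the data were examined, and the share of each differed between the siRNAs. Between the siR164 and siR386 sites lay 24.9% ± 1.13 of coverage after siR164, against 16.1% ± 1.22 after siR386 and 14.1% ± 2.73 after siR739 (SD, n = 3). The stretch between the siR386 and siR739 sites held most of the coverage in each group, at 73.2% ± 0.83 after siR164, 80.8% ± 1.60 after siR386 and 76.7% ± 2.85 after siR739. After the siR739 site the share was 1.05% ± 0.14, 1.92% ± 0.43 and 4.09% ± 0.43 in the same order, and the 3 siR739 libraries, from 3.82% to 4.58%, lay above all others. Before the siR164 site the share was 0.824% ± 0.44 after siR164, 1.18% ± 0.31 after siR386 and 5.06% ± 2.72 after siR739. Each of the 4 shares differed between the 3 groups, with an adjusted exact permutation p of 0.0143 (raw exact p from 0.00357 to 0.0143, 4 segments). The 4 shares of a library add up to 100%, so a change in 1 segment brings changes in others and the tests are not separate. Raw coverage before the siR164 site was 3.36 ± 2.14, 1.96 ± 0.76 and 2.58 ± 0.57 reads per position after siR164, siR386 and siR739, without a detectable difference (exact p = 0.539). After the siR739 site it was 24.3 ± 16.7, 15.7 ± 3.47 and 11.9 ± 3.99 reads per position in the same order, also without a detectable difference (exact p = 0.414). In the authors' deposited table of 21-, 22- and 24-nt reads, the stretch before the siR164 site held 1.24%, 1.00% and 0.982% of the column sums after siR164, siR386 and siR739. That table gave 24.5%, 15.6% and 14.2% between the siR164 and siR386 sites, 70.4%, 78.8% and 79.3% between the siR386 and siR739 sites, and 0.339%, 0.336% and 0.848% after the siR739 site, where it ends 20 positions short of the contig. Calls before the siR164 site and between the siR386 and siR739 sites were lost without siR164 replicate 1 (adjusted exact p = 0.0536 for both), siR164 replicate 3 (0.0607 for both), siR386 replicate 4 (0.0607 and 0.0524) or siR386 replicate 5 (0.05 for both). With the mean coverage of positions 1 to 100 subtracted, the share before the siR164 site kept its call when values below 0 were set to 0 (0.476%, 0.484% and 2.61%, adjusted exact p = 0.0357) and lost it when they were kept (0.387% ± 0.045, 0.263% ± 0.39 and 1.85% ± 2.75, SD, n = 3, adjusted exact p = 0.543). When they are kept, positions 1 to 100 add up to 0 in every library by construction, so only the rest of the segment was compared.

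**Figure D3:**
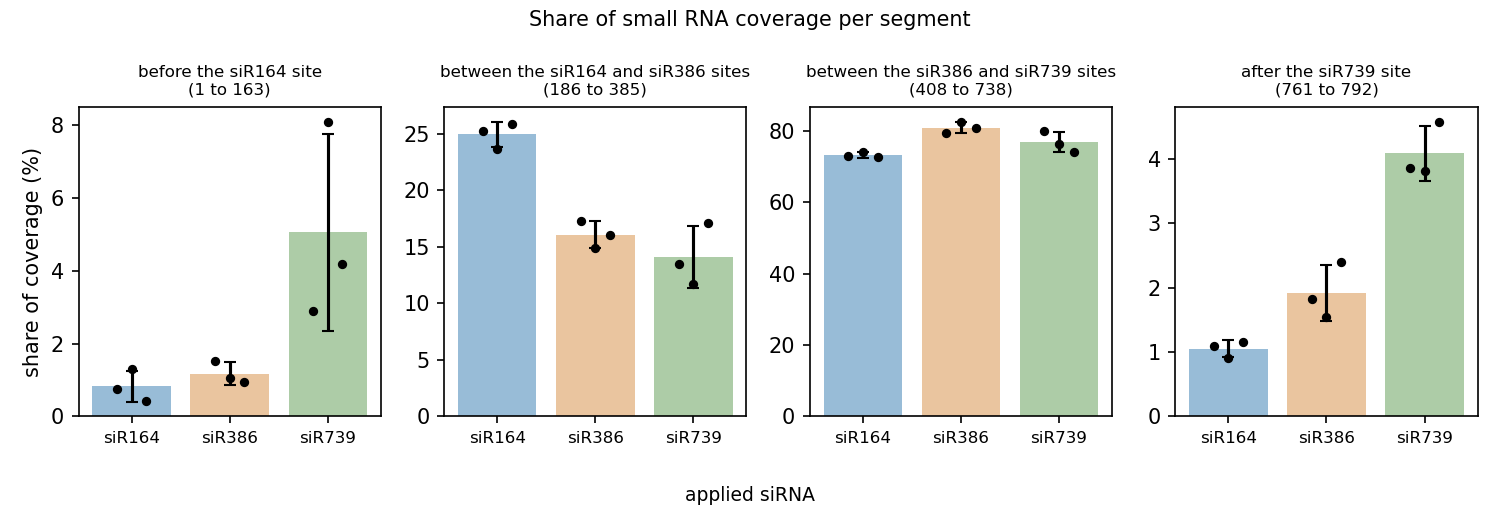
Share of small RNA coverage (%) in each of the 4 segments set by the siRNA sites, with 1 panel per segment and the applied siRNA on the horizontal axis. Bars and error bars are the mean ± SD of 3 libraries and points are libraries. The share between the siR164 and siR386 sites was 24.9% after siR164, 16.1% after siR386 and 14.1% after siR739.

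Relative to its own site, each siRNA had a different division of coverage, which depends on where that site lies on the contig. After siR164, 99.2% ± 0.44 of coverage outside the sites lay 3' of the siRNA's site, after siR386 82.8% ± 1.48 and after siR739 4.09% ± 0.43 (SD, n = 3). The sides differ in length, with 563 positions 3' of the siR164 site, 363 on each side of the siR386 site and 32 positions 3' of the siR739 site. Per position, coverage 3' of the site was 127 ± 82.1 reads against 3.36 ± 2.14 on the 5' side after siR164. It was 63.0 ± 26.9 against 12.9 ± 4.46 after siR386, and 11.9 ± 3.99 against 13.0 ± 4.65 after siR739. Corrected for length in this way, the 3' side held 97.2% after siR164, 82.8% after siR386 and 48.0% after siR739. Libraries of the other siRNAs were divided at the same points for reference. Of their coverage, 98.8% after siR386 and 94.9% after siR739 lay 3' of the siR164 site, 74.2% after siR164 and 80.8% after siR739 lay 3' of the siR386 site, and 1.05% after siR164 and 1.92% after siR386 lay 3' of the siR739 site. No test between groups was made of these values.

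Profiles after siR386 and siR164 differed in 1 of 26 windows outside the sites. Window 326–350, 5' of the siR386 site, fell by 0.72 on the log2 scale (SE 0.14, limma adjusted p = 0.00823), from 6.96% ± 0.50 after siR164 to 4.18% ± 0.12 after siR386 (SD, n = 3). At an unadjusted p under 0.05 there were 10 such windows. In raw coverage, not scaled for library size, 7 windows were lower after siR386 and 0 were higher (limma). The largest differences were in windows 201–225 (log2 difference −2.08, 24.2 ± 10.9 against 5.91 ± 4.54 reads), 326–350 (−1.96), 301–325 (−1.95), 276–300 (−1.87) and 251–275 (−1.83), all between the siR164 and siR386 sites. These calls rest on a spread pooled over windows that move together with the level of their library; without that pooling limma called 0 (8 at an unadjusted p under 0.05), and the test of the level between libraries gave an exact p of 0.2. With quantile normalization the count in raw coverage became 1 higher and 1 lower, and in shares 1 higher and 1 lower. Without siR164 replicate 1 or 3, limma called 0 windows in shares (4 at an unadjusted p under 0.05 in each case), while 2 were called without siR386 replicate 4, siR386 replicate 6 or siR739 replicate 9 and 3 without siR739 replicate 8. In raw coverage, limma called 0 without siR164 replicate 1, siR164 replicate 3, siR386 replicate 6 or siR739 replicate 9 (7, 10, 7 and 9 at an unadjusted p under 0.05), 1 without siR386 replicate 4 and 14 without siR164 replicate 2.

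Profiles after siR739 and siR164 differed in 15 of 26 windows, 9 with a higher and 6 with a lower share after siR739 (limma, adjusted p under the threshold of 0.05). The lower windows lay between position 226 and position 525. Window 326–350 fell by 1.19 (SE 0.14, limma adjusted p = 5.72e-05), from 6.96% ± 0.50 to 3.01% ± 0.54 (SD, n = 3), and window 301–325 fell by 1.16, from 3.62% ± 0.65 to 1.60% ± 0.47. Towards the siR739 site, window 676–700 rose from 5.53% ± 0.36 to 7.72% ± 0.34 and window 701–725 from 3.28% ± 0.30 to 5.56% ± 0.98. Past the site, window 776–792 rose from 0.321% ± 0.0049 to 1.47% ± 0.41 (log2 difference 1.87, SE 0.30, limma adjusted p = 0.000403). The other 6 higher windows cover positions 1 to 150, with the largest log2 differences in windows 26–50 (2.43, SE 0.46), 126–150 (2.34, SE 0.54), 101–125 (1.97, SE 0.61) and 51–75 (1.86, SE 0.46). Each of them held between 0.408% and 1.44% of coverage after siR739. Windows 126–150 and 101–125 held 2.94% and 1.81% in siR739 replicate 8, against at most 0.795% and 0.391% in replicates 7 and 9, and without replicate 8 their log2 differences were 1.69 (SE 0.44, limma adjusted p = 0.0106) and 1.21 (SE 0.44, limma adjusted p = 0.0350). With quantile normalization 11 windows were called, 4 higher and 7 lower, and of windows 1 to 150 the call remained at 126–150 (log2 difference 1.61, limma adjusted p = 0.0345), while window 1–25 turned to −0.055. With the mean coverage of positions 1 to 100 subtracted from each library, 9 windows were called, 3 higher and 6 lower. Of the 9 higher windows, the 5 of positions 1 to 125 were then too low to be tested, and window 126–150 had a log2 difference of 1.86 (SE 0.79) against 2.34 (SE 0.54) before and did not pass (limma adjusted p = 0.0657). Of the 6 windows that hold part of a site, 3 also differed, 726–750 and 751–775 with a higher share after siR739 and 376–400 with a lower share.

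In raw coverage, 19 windows were lower after siR739 than after siR164 and 0 higher (limma). The largest differences were in windows 326–350 (log2 difference −3.91, 202 ± 133 against 10.97 ± 2.70 reads), 301–325 (−3.78), 351–375 (−3.51), 276–300 (−3.22) and 226–250 (−3.15). The spread was again pooled over windows that move together; without that pooling limma also called 19, while the level between libraries had an exact p of 0.1. Windows of positions 1 to 150 had log2 differences from 0.085 to 0.61 in raw coverage and did not pass, and neither did window 776–792 (−0.59). With quantile normalization the raw coverage gave 5 higher and 7 lower windows. Without siR164 replicate 1, 9 windows were called in shares, 6 higher and 3 lower.

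Profiles after siR739 and siR386 differed in 6 of 26 windows, 4 with a higher and 2 with a lower share after siR739 (limma). Window 776–792 rose from 0.582% ± 0.17 to 1.47% ± 0.41 (log2 difference 1.20, SE 0.30, limma adjusted p = 0.0129). Windows 126–150 (log2 difference 2.17, SE 0.54), 26–50 (1.77, SE 0.46) and 1–25 (1.73, SE 0.55) also rose, the first from 0.195% ± 0.14 to 1.44% ± 1.30 (log2 difference 1.52, SE 0.44, limma adjusted p = 0.0357 without siR739 replicate 8). Window 576–600 fell by 0.33 (SE 0.078), from 12.2% ± 0.49 to 9.72% ± 0.76, and window 326–350 fell by 0.47 (SE 0.14), from 4.18% ± 0.12 to 3.01% ± 0.54. Of the windows that hold part of a site, 751–775 had a higher share after siR739 (log2 difference 0.96, limma adjusted p = 0.0129). In raw coverage 11 windows were lower after siR739 and 0 higher, with the largest differences in windows 326–350 (−1.95), 651–675 (−1.90), 576–600 (−1.86), 301–325 (−1.83) and 426–450 (−1.77). Without pooling of the spread over windows limma called 0 in raw coverage (12 at an unadjusted p under 0.05) and 3 in shares, 2 higher and 1 lower, and the level between libraries had an exact p of 0.1. With quantile normalization limma called 0 windows in shares and 0 in raw coverage (7 and 8 at an unadjusted p under 0.05), and 0 in shares without siR386 replicate 5 (8 at an unadjusted p under 0.05). With the coverage of positions 1 to 100 subtracted, window 326–350 kept its call in shares, at −0.55 (SE 0.15, limma adjusted p = 0.0448), and 8 windows had an unadjusted p under 0.05. Windows of positions 1 to 125 were then too low to be tested. Windows 776–792 (1.16, SE 0.36, limma adjusted p = 0.0511), 576–600 (−0.25, SE 0.074, 0.0511) and 126–150 (2.04, SE 0.79, 0.0711) kept their direction and did not pass. In raw coverage limma called 0 windows without siR386 replicate 4, siR386 replicate 5, siR739 replicate 8 or siR739 replicate 9 (12, 8, 6 and 9 at an unadjusted p under 0.05), 7 without siR386 replicate 6 and 18 without siR164 replicate 1.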

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

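All tests in this part were chosen after the values had been seen. The sites of the applied siRNAs held coverage of 0 in the files, and 4 places stood out because a library had coverage there or a sharp block at the edge, although the same sites are at 0 in the other libraries or the positions beside them are far lower. The shares and levels include this coverage, and in siR386 replicate 6 it made windows 151–175 and 176–200 hold 2.75% and 2.43% of the library's coverage. With the zeroed stretches masked alike in all libraries the counts of windows in shares were 1, 17 and 7 for siR386 against siR164, siR739 against siR164 and siR739 against siR386. In siR386 replicate 6 the 22 positions of the siR164 site had a mean coverage of 43.6 and a maximum of 48, with 4 reads at the position before and 4 at position 188. In siR739 replicate 8 the first 2 positions of the siR164 site had a coverage of 11, against 3 at the position before. In siR164 replicate 1 the first 2 positions after the siR386 site had a mean coverage of 621 (637 and 605), against 182 at position 410, where the other 8 libraries reached between 9 and 201. In siR386 replicate 4 the first 2 positions after the siR164 site had a mean coverage of 20.5 (25 and 16), against 4 at position 188.

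The block at the siR164 site of siR386 replicate 6 was weighed further. A wrong label for this library is argued against by its step at the 3' edge of the siR386 site, a log2 ratio of 2.83, which was above the highest of the 6 libraries of the other siRNAs (1.38). Reads of the siR164 siRNA itself in this library remain a candidate explanation. The rise over 3 positions at the start of the block was 3.17 on the log2 scale, against at most 1.32 elsewhere outside the zeroed sites. The block was flagged for its sharp edge, so this rise describes it and adds no separate support. Whether such reads came from the plant material, from library preparation or from the assignment of reads to libraries was not tested, and no biological explanation was tested.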

How the results depend on the processing

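Masking the sites and subtracting coverage of positions 1 to 100 (values below 0 set to 0 or kept) were set after seeing the data. So were the 5' and 3' edges and limma without moderation, unlike most other settings. The test of the level over 3 groups kept its call under all settings run, as did the segment between the siR164 and siR386 sites and that after the siR739 site, except when distinct positions replaced coverage. With distinct positions each of the 4 segments had an adjusted exact p of 0.975, but this measure is nearly saturated, with 694 to 721 positions covered in all libraries except siR164 replicate 3 (609), and decides nothing. Of the recalculations, without 39 of pairwise levels, which could not cross the threshold, 173 stayed on their side of the threshold or within 1.5 times the count, 20 newly passed or gave a higher count, 56 no longer passed or gave a lower count, and 2 values without a test moved. Counts of profile windows were 1, 15 and 6 for siR386 against siR164, siR739 against siR164 and siR739 against siR386. With 50-nt windows, of which 11 were tested, they were 2, 5 and 4, and with single positions, of which 714 were tested, 12, 322 and 122. Quantile normalization gave 2, 11 and 0 (7 at an unadjusted p under 0.05 for the last), and subtracting the coverage of positions 1 to 100, which leaves 21 windows to test, gave 1, 9 and 1. For siR739 against siR164 they gave 4 higher and 7 lower, and 3 higher and 6 lower, in place of 9 and 6, but windows 1 to 125 could not be tested after the subtraction. Limma without moderation gave 1, 14 and 3 in shares and 0, 19 and 0 in raw coverage (8 and 12 at an unadjusted p under 0.05 for the zeros). For siR386 against siR164, limma without the trend called 2 and the fit of those 2 groups alone 3. Counts of windows in raw coverage were 7, 19 and 11. They were 3, 8 and 6 with 50-nt windows, 177, 532 and 285 with single positions, and 2, 12 and 0 (8 at an unadjusted p under 0.05) with quantile normalization, which removes the difference in level by construction (the median log2 difference over windows was −1.04, −2.51 and −1.38 before it). The fit of the compared groups alone gave 0 (8 at an unadjusted p under 0.05) for siR386 against siR164 and 17 for siR739 against siR386, where a pseudocount of 10 gave 0 (12 at an unadjusted p under 0.05). For settings that keep the same windows, other than quantile normalization, the cause was not tested. Length correction moved the share 3' of the own site to 97.2% for siR164 and 48.0% for siR739. The 3' edges gave 1.54, 1.69 and 0.23 in place of 2.13, 0.34 and 1.25 for siR164, siR386 and siR739.

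Leaving out each library in turn gave 0 to 3, 9 to 17 and 0 to 8 profile windows and 0 to 14, 19 to 19 and 0 to 18 windows in raw coverage, in the order above. Lows of 0 in profile windows came without siR164 replicate 1 or 3 (4 at an unadjusted p under 0.05 in each) and without siR386 replicate 5 (8). In raw coverage they came, for siR386 against siR164, without siR164 replicate 1 or 3, siR386 replicate 6 or siR739 replicate 9 (7, 10, 7 and 9 at an unadjusted p under 0.05) and, for siR739 against siR386, without siR386 replicate 4 or 5 or siR739 replicate 8 or 9 (12, 8, 6 and 9). The adjusted exact p ranged from 0.0143 to 0.0607 before the siR164 site, 0.00714 to 0.0357 between the siR164 and siR386 sites, 0.0143 to 0.0607 between the siR386 and siR739 sites and 0.00714 to 0.0214 after the siR739 site. With values below 0 kept after the subtraction, the adjusted exact p before the siR164 site was 0.543. Lost calls on leaving out came without siR164 replicate 1 or 3 or siR386 replicate 4 or 5. Edge steps ranged from 1.51 to 2.74 at the siR164 site, 0.26 to 0.46 at the siR386 site and 1.21 to 1.30 at the siR739 site. An exact test of 2 against 6 libraries cannot give a p under 0.0357, so part of the lost calls there come from the fewer samples. The difference in profile similarity ranged from 0.036 to 0.066, with an exact p of 0.0571 without siR164 replicate 1 or 3. The exact p of the level over 3 groups ranged from 0.00357 to 0.0143, and the pairwise log2 differences from −1.60 to −0.74, −3.08 to −2.22 and −1.73 to −1.18. Shares 3' of the own site ranged from 99.0% to 99.4%, 82.1% to 83.6% and 3.84% to 4.22%. No paired analysis was possible because the groups share no replicate numbers. Size classes, strands, 21-, 22- or 24-nt reads alone, 22-nt reads at the sites, the share in place of the level at the sites, and count models with their scaling factors were planned and not run, since coverage of all lengths on both strands does not separate them.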

Other observations

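The test of a 21-nt register below, and the random draws of libraries at the lowest depth, were set before their results were seen. The other tests in this part were chosen after. Within the stretch between the siR386 and siR739 sites the profiles had a common outline: window 601–625, named after its values were seen, held 1.90% ± 0.15 of coverage after siR164, 2.04% ± 0.093 after siR386 and 2.22% ± 0.41 after siR739 (SD, n = 3), next to the 2 windows with the highest shares. In the authors' deposited table the maximum lay at position 568 for siR164, 566 for siR386 and 568 for siR739. Single libraries peaked at positions 576 to 578 after siR164 and siR386, at 577 in siR739 replicate 9, alike at 575, 576 and 763 in siR739 replicate 8, and at the last position before the siR739 site in siR739 replicate 7.

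The profiles differed between siRNAs, and 1 hypothesis is that the applied siRNA shapes where secondary small RNAs arise. A lower depth after siR739 adds noise and could lower the correlation between groups. Random draws of 297 reads from the window shares of each library left an exact one-sided p under 0.05 in 56 of 100 draws. Such draws add sampling noise to the noise already in each library, so they decided nothing. A chi-square test between the summed libraries takes depth into account, though it covers counting error only. It gave 6.77 per degree of freedom for siR386 and siR164, 12.1 for siR739 and siR164 and 3.82 for siR739 and siR386, and at least 3.85, 8.30 and 2.34 without any 1 library (p at most 0.000172), against at most 1.30 between a replicate and the other 2 of its group. This argues against counting error at a lower depth as the whole cause in all 3 pairs. However, single library pairs went down to 1.23, 1.91 and 1.12, with a chi-square p under 0.05 in 7, 9 and 4 of 9 pairs. The last 4 were siR739 replicate 8 with each siR386 library, and siR739 replicate 9 with siR386 replicate 5. Where profiles differ, the statistic grows with the number of reads, so summed groups and replicates are not compared at like depth. A background that takes a larger share at low signal is not covered by this test. Reads of the applied siRNA beside the zeroed sites are argued against as the source of the higher share between the siR164 and siR386 sites after siR164, which with 30 positions on each side of the sites left out was 20.4% ± 1.23, against 12.7% ± 1.07 after siR386 and 11.1% ± 1.60 after siR739 (SD, n = 3, exact p = 0.00714). Of the 10 splits of the 6 libraries in each pairwise window test, 1, the real split, gave as many windows (1, 15 and 6 in shares and 7, 19 and 11 in raw coverage, in the order siR386 against siR164, siR739 against siR164 and siR739 against siR386), and the highest other split gave 0, but 10 splits are too few for a share under 0.05. Plants, leaves and spraying runs that differ between the siRNAs stay open, since the labels do not separate them from the siRNA.

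The higher shares after siR739 at the ends of the contig were weighed separately. Before the siR164 site a background of reads that does not scale with silencing may account for the share. Raw coverage there was 1.30 times as high after siR164 as after siR739, against 7.68 times over the whole contig. The siR164 replicates 1 to 3 held 5.67, 2.96 and 1.44 reads per position there, so that ratio leans on replicate 1. In siR164 replicate 3 coverage was 0 at positions 1 to 100, so such a background was not alike in all libraries. The authors' deposited table of 21-, 22- and 24-nt reads shows no higher share there after siR739 (0.982% against 1.24% after siR164). Its shares include the sites in the sum, and its last entries before the site average over positions within the site. With the coverage of positions 1 to 100 subtracted and values below 0 set to 0, which leaves scatter above 0, the share stayed at 2.61% after siR739 against 0.476% and 0.484% after siR164 and siR386 (exact p = 0.0357). With values below 0 kept the exact p was 0.543, and the share was 5.01% in siR739 replicate 8 but 0.481% and 0.0524% in replicates 7 and 9, so a background at that level could not be told apart from a change in profile. Positions 1 to 100 then add up to 0 in every library by construction, so a difference between siRNAs there could not show in that test. After the siR739 site raw coverage was 2.04 times as high after siR164 as after siR739 and did not differ detectably between the 3 groups (exact p = 0.414). The siR164 replicates 1 to 3 held 42.8, 10.5 and 19.6 reads per position there, so that ratio leans on replicate 1. A background with a level of its own there could not be told apart from a change in profile. The authors' deposited table, which ends before the contig does, had a higher share there after siR739 (0.848% against 0.339% after siR164 and 0.336% after siR386). A background at the level of positions 1 to 100 is argued against, because with the coverage of positions 1 to 100 subtracted the share was 4.04% ± 0.49 after siR739, 1.82% ± 0.46 after siR386 and 0.988% ± 0.21 after siR164 (SD, n = 3, exact p = 0.00357). Reads of siR739 left beside the zeroed site are argued against for the last 8 positions only, from 785. The share there was 0.613% ± 0.22 after siR739, against 0.228% ± 0.064 after siR386 and 0.102% ± 0.0095 after siR164 (SD, n = 3, exact p = 0.00357, the smallest the partitions can give). The whole segment after the site held 4.09% after siR739, so such reads stay open for the positions nearer the site.

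If Dicer-like enzymes cut in 21-nt steps from the end set by the applied siRNA, start positions aligned to each siRNA's own site should share a register. The single-position values, recovered from the authors' deposited table by reading each entry as a mean over 10 positions, were folded into 21 registers and correlated between columns, in fixed coordinates and after alignment to the own site. The correlation across the 21 registers, which are not replicates, was 0.847, 0.600 and 0.525 in fixed coordinates for siR386 and siR164, siR739 and siR164, and siR739 and siR386. After alignment it was −0.077, −0.188 and −0.015. The smallest difference was 0.540, in favour of fixed coordinates in all 3 pairs, so no shared register was seen after alignment. The columns also share peaks in fixed coordinates, with the largest single-position value at 575 for siR164, 572 for siR386 and 572 for siR739. Alignment to the own sites moves such shared peaks apart, which lowers the correlation with or without steps from the site. Reads of several lengths are summed in that table as well. The comparison therefore cannot decide whether such steps occur.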
